A study of Homo sapiens with 24 samples.

How the data were processed

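RNA was measured on 24 Illumina bead arrays from 4 human breast cancer cell lines, MDA-MB-468, BT549, SUM149 and HCC1395. According to the labels each line carried a different p53 missense substitution and was transfected 2 times, 24 h apart, with 50 nM of control siRNA or of an siRNA against TP53, using a lipid reagent, and processed 48 h after the second transfection. MDA-MB-468 and HCC1395 were grown in DMEM, BT549 in RPMI and SUM149 in DMEM:F12, so that the medium differed between some lines but not between the siRNAs within a line. Each line and siRNA had 3 arrays, which the labels call biological replicates. The 8 groups of 3 arrays were taken from the sample titles.

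The deposited non-normalized table gave a summarised signal intensity per probe and array on a linear scale, with no background subtraction and no normalization between arrays. Per the file headers it also gave a detection p-value per probe and array, which compares the probe with the negative control beads. The processing notes name GenomeStudio without a version. A further value table from the authors held the same intensity values after quantile normalization between all arrays, on a linear scale. Its columns all had a median of 219.8, and each had a rank correlation of 1 with the same sample in the non-normalized table. The non-normalized table was used for the reported values, and the authors' table served as an alternative.

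Intensities were processed with neqc of limma 3.58.1 in R 4.3.3. This step models the background from the negative controls as inferred from the detection p-values, adds an offset of 16, normalizes quantiles between the 24 arrays and takes log2. Quantile normalization gives every array the same distribution, so a shift of most transcripts in one direction could not be seen. The median log2 change of all tested genes lay at or under 0.025 in size in every comparison of the reported fit. Of 47314 probes, 26317 had a detection p-value below 0.05 on at least 3 arrays and were kept. The probe-to-gene table listed 30117 probes, of which 30109 had 1 gene and 8 had several genes, which were left out. The other 17197 probes were not listed and entered no gene comparison. The gene identifiers of 30070 listed probes matched the human gene annotation on GRCh38.p14, which was used for gene names only, and 0 symbols changed. Of the kept probes, 19140 had a gene name. The brightest probe of each gene, by its mean over all arrays, represented the gene, which left 14031 genes. Probe positions in the genome were not used here.

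The number of arrays limits the precision of every value. Arrays detected between 17945 and 20605 probes, or 37.9% to 43.5%, with raw median intensities between 194.3 and 242. Array pairs within a group correlated at 0.980 to 0.994 across genes, and no pair held the same values throughout. The BT549 control arrays had the lowest of these correlations, from 0.980 to 0.987. Each gene was fitted with limma over the 8 groups, with default empirical Bayes settings, 16 residual and 3.26 prior degrees of freedom, and 1 estimate of the spread shared by all groups. The contrasts were TP53 siRNA minus control siRNA within each line, the mean of these 4, their pairwise differences, and an F test of the 3 line-by-siRNA interaction terms. P-values were adjusted by Benjamini and Hochberg over the 14031 genes, and an adjusted p below 0.05 was called a change. Overlaps of calls between pairs of lines were tested with Fisher's exact test across genes. Tests of overlaps and correlations across genes treat genes as independent, which they are not.

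A total of 21 gene lists was fixed before the data were examined, together with the fit, the thresholds, the rule for named genes and the alternatives, except those named as added later. The lists were proteasome 20S core, proteasome 19S regulator, proteasome assembly and activators, immunoproteasome, ubiquitin and segregase, NRF2 targets, p53 targets, G2/M and mitosis, DNA replication and G1/S, cholesterol synthesis, nucleotide synthesis, interferon response, NF-kB and cytokines, unfolded protein response, heat shock chaperones, hypoxia and glycolysis, mesenchymal markers, epithelial markers, leukocyte markers, ribosomal proteins, and p53 family and MDM. They were tested against all other genes with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the members of a list move one way on balance and makes no comparison with other genes. List p-values were adjusted over the 21 lists within a contrast, and over 126 tests for the differences between lines. The proteasome lists were included because the study's title names the proteasome, so their choice was informed by the study, while the direction came from the arrays.

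Named genes followed a rule. For each line these were the 8 genes that rose most and the 8 that fell most among those with an adjusted p below 0.05 whose 3 values under one siRNA all lay beyond the 3 under the other. For the average they were the 12 that rose most and the 12 that fell most with an adjusted p below 0.05 and the same sign in all 4 lines. For the difference between lines they were the 8 genes with the smallest interaction p, and for each list up to 4 members with the smallest p in the contrast described. Other list members named in the text were chosen after their values were seen.

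Log2 changes carry the standard error of the limma fit, and group levels carry the SD of 3 arrays. The standard error rests on the spread of arrays within groups, shared by all lines. For the average it therefore leaves out the spread between lines. Where a gene was detected on none of the 3 arrays of one group, its fold is given as a lower bound. The bound compares the other group's mean with the lowest intensity that counted as detected on each array, or with the gene's own value where that was higher. Averages and list medians were also computed with such genes at their bound, and with 0 where neither group was detected. The fit was tested on simulated data with the same group structure and 1 spread per gene shared by all arrays. Genes were simulated as independent, and far fewer of them changed than passed in the real arrays. In a single line it recovered 34.3% of genes changed by 1.5-fold, 71.6% of those changed by 2-fold and 100% of those changed by 4-fold in MDA-MB-468, with 8 false calls. In BT549 it recovered 23.5%, 78.8% and 100%, with 3 false calls. The average over lines recovered 91.2% at 1.5-fold and 100% at 2-fold and at 4-fold, with 14 false calls. The test of a difference between lines recovered 12.1%, 55.9% and 90.9%, with 1 false call, so in this setting it missed many differences under 2-fold. The adjustment is less strict where more genes change, so these shares need not carry over to the real arrays. The real BT549 control arrays differed more among replicates than any other group. The simulation did not include this, so its false calls in BT549 need not carry over either. A simulated list of independent genes shifted in all lines had a camera p of 1.63e-30 and an unshifted list 0.479.

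The alternatives were no background correction, neqc within each line, the authors' quantile-normalized values, an offset of 50, no filter and a stricter filter on dim probes, the mean of a gene's probes, a replicate block, array weights, a trended and robust empirical Bayes step, a fit on the 6 arrays of one line, an adjusted p below 0.01, a change of at least 1.5-fold, the other list tests, and leaving out each array in turn. Comparisons without the 2 BT549 control arrays of lowest weight, and an average without BT549, were added after the data were seen. Arrays were also regrouped, with 10 splits per line and 100 regroupings of the arrays within lines for the results over several lines. The 7177 kept probes without a listed gene were fitted separately.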

Results

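Transcripts were measured in 4 established human breast cancer cell lines after transfection with an siRNA against TP53, the gene of the p53 tumour suppressor, or with a control siRNA. According to the labels each line, MDA-MB-468, BT549, SUM149 and HCC1395, carried a different p53 missense substitution, and the title of the study asks for a program shared by such mutants that involves the proteasome. The series held 24 arrays in 8 groups of 3, of which each detected 37.9% to 43.5% of its 47314 probes. Changes are log2 ratios of TP53 siRNA over control siRNA, from 3 arrays per group, and adjusted p-values are those of limma over 14031 genes. Values after ± are standard errors of the limma fit. They rest on the spread within groups pooled over all lines, so they do not measure the spread of a single line. Lower levels after TP53 siRNA are written as falls, higher levels as rises, and single genes are said to have risen or fallen where the adjusted p was below 0.05. The probe table used here listed no probe for TP53, so TP53 itself was not analysed here and the knockdown and the siRNA labels could not be checked through their target.

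On average over the 4 lines proteasome subunits and DNA replication genes were lower with TP53 siRNA than with control siRNA. Genes of cholesterol synthesis and several histone genes were higher. In MDA-MB-468 and HCC1395 interferon genes were lower with TP53 siRNA, but a rise set off by the control siRNA could not be told apart from a fall. Among the large falls in all 4 lines was that of ICMT, the enzyme that methylates prenylated proteins, at -2.33 ± 0.06 (adjusted p = 2.8e-16), and it ranged from -2.91 in BT549 to -1.98 in SUM149. SPRING1, a regulator of the SREBP pathway of sterol synthesis, was at least 3.10-fold lower on average, a bound because it was not detected after TP53 siRNA in MDA-MB-468, BT549 and SUM149. POLR1H, a subunit of RNA polymerase I, changed by -1.87 ± 0.06. HMGCS1, an enzyme of the mevalonate pathway, rose by 1.38 ± 0.08 (adjusted p = 4.2e-11), from 1.09 to 1.57 in the single lines. The histone gene H2BC5 rose by 1.47 ± 0.04 (adjusted p = 9.95e-16), from 0.60 in HCC1395 to 2.02 in BT549.

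On average 2478 genes rose and 2563 fell, or 35.9% of those tested, of which 253 rose and 348 fell by at least 1.5-fold. In all 4 lines 73 genes rose and 154 fell, where 0.441 and 0.712 would be expected if the lines were independent. The contrasts of a gene shared 1 estimate of its spread, so the calls were not independent and these expected counts may be too low. Large falls in every line also included those of the importins IPO5 at -1.85 ± 0.11 and IPO8 at -1.54 ± 0.07 and of the Rho regulator ARHGAP19 at -1.84 ± 0.08. The flippase subunit TMEM30A changed by -1.70 ± 0.12 and the ubiquitin ligase adaptor FBXW11 by -1.54 ± 0.04. TMEM87B was at least 2.38-fold lower on average and TLNRD1 at least 2.51-fold lower, since after TP53 siRNA the former was not detected in BT549, SUM149 and HCC1395 and the latter not in BT549. ERLIN2, a protein of the endoplasmic reticulum, changed by -2.25 ± 0.11 on the probe used, and its other probes ranged from -0.20 to 0.05. SEMA4F, a semaphorin, changed by -1.55 ± 0.07 on its brighter probe and by 0.17 on the other. The rises on average with the same sign in all 4 lines included PGM2L1 at 1.70 ± 0.14 and the histone gene H2AC6 at 1.25 ± 0.05. The actin-binding protein TAGLN was among them at 1.35 ± 0.07. VPS4B, an ATPase of membrane scission, rose by 1.25 ± 0.05, from 0.51 in MDA-MB-468 to 2.25 in BT549. REV3L, the catalytic subunit of DNA polymerase zeta, rose by 1.17 ± 0.20. AMMECR1 rose by 1.16 ± 0.07 and NUPR1 by 1.12 ± 0.08. The histone gene H4C8 was at least 2.61-fold higher on average, being undetected with control siRNA in SUM149. S100P was 2.02-fold higher on average with BT549, where it was not detected under either siRNA, counted as unchanged. TAGLN, REV3L and S100P did not pass in every line and were not among the 73 genes above. The ubiquitin ligase NEDD4 rose by 1.71 ± 0.11 on the probe used, from 0.82 in SUM149 to 2.85 in BT549. Another of its probes changed by 0.13. Near-identical histone genes may share probes, so a histone symbol may stand for more than 1 gene. The siRNA sequences were not used here.

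**Figure D1:**
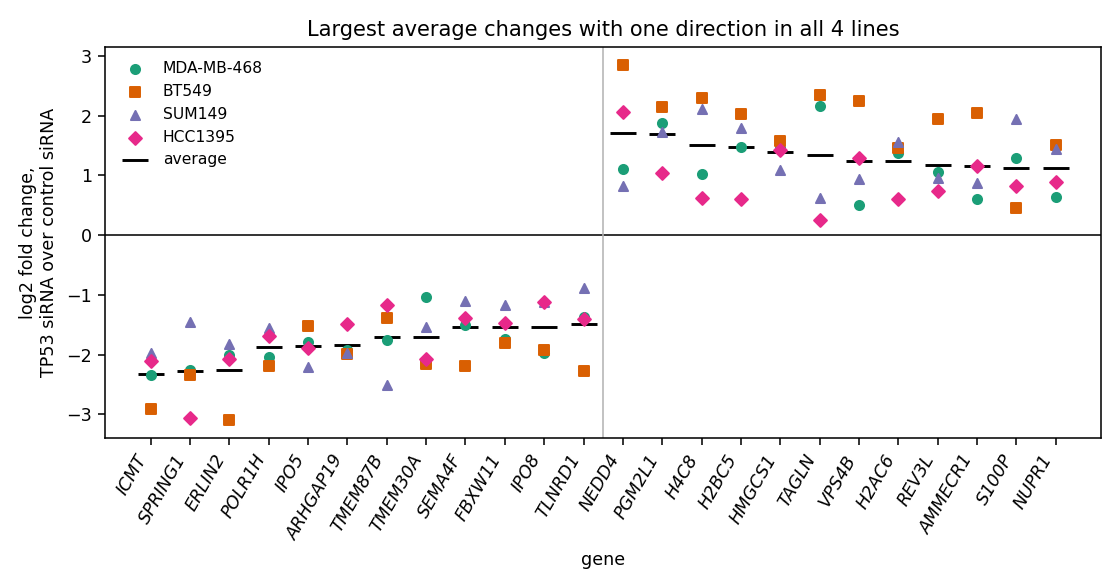
Log2 change (TP53 siRNA over control siRNA, vertical axis) of the 12 genes that fell most and the 12 that rose most on average with one direction in all 4 lines (horizontal axis). Each coloured marker is one line from 3 arrays per group, and each black dash is the average, such as -2.33 for ICMT and 1.71 for NEDD4. Values are fitted, and those of SPRING1, TMEM87B, TLNRD1, H4C8 and S100P include lines in which a group was not detected.

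Proteasome genes fell, with a small group of subunits well ahead of the rest. Of the 13 measured subunits of the 20S core, the proteolytic barrel, 10 fell and 0 rose on average, and the counts were 10 and 0 when adjusted over the list alone. PSMA2 changed by -0.86 ± 0.08 and PSMA1 by -0.55 ± 0.04, followed by PSMA5 at -0.32 ± 0.05 and PSMA6 at -0.26 ± 0.04. The list median was -0.17 (camera adjusted p = 4.51e-05, and adjusted p = 0.0104 with an estimated correlation). Of 16 subunits of the 19S regulator, which recognises and unfolds substrates, 4 fell and 0 rose, also when adjusted over the list alone. PSMC1 changed by -0.72 ± 0.04 and PSMD12 by -0.61 ± 0.06, while the list median was -0.10 (camera adjusted p = 0.0119). Of 100 regroupings of the arrays within lines, 6 gave a p as small for this list, the real one included. The 5 measured immunoproteasome genes, whose products replace or bind core subunits after interferon, all fell, among them PSMB9 at -0.60 ± 0.06, PSMB8 at -0.45 ± 0.05 and PSMB10 at -0.44 ± 0.05 (list median -0.44, camera adjusted p = 4.34e-05). The line median of this list was lowest in MDA-MB-468 (-0.96), and the list did not pass in BT549 (median -0.33, 3 fell, camera adjusted p = 0.0618). Of 11 assembly factors and activators 2 fell, PSMD10 at -0.55 ± 0.05 and PSME4 at -0.23 ± 0.07, and the list did not pass (median -0.06, adjusted p = 0.328, with fry 0.000123). PSMA1, PSMA2, PSMC1 and PSMD10 fell in each of the 4 lines.

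By line, the 20S list had a median of -0.13 in MDA-MB-468 (2 subunits fell, camera adjusted p = 0.0183), -0.23 in BT549 (6 fell, 0.00286), -0.18 in SUM149 (6 fell, 0.0136) and -0.26 in HCC1395 (4 fell, 7 when adjusted over the list alone, 1.50e-05). The call held in HCC1395 with an estimated correlation (adjusted p = 0.00531 with an estimated correlation), while the corresponding adjusted p-values with an estimated correlation were 0.0955 in MDA-MB-468, 0.0506 in BT549 and 0.0972 in SUM149. Without the MDA-MB-468 TP53 siRNA replicate 2 the adjusted p in that line was 0.0607. The 19S list passed in SUM149 (median -0.16, 3 fell, 4 when adjusted over the list alone, adjusted p = 0.0201, and adjusted p = 0.0588 with an estimated correlation) and in HCC1395 (median -0.09, 2 fell, adjusted p = 0.00905), but not in MDA-MB-468 (median -0.05, 0.307, with fry 0.00184) or BT549 (median -0.14, 0.105, with fry 9.84e-07). No pairwise difference between lines passed for either list. PSMA7, PSMC5, PSMD7 and PSMD13 had no probe in the table used and were not analysed here, and the proteasome lists were chosen from the study's title.

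**Figure D2:**
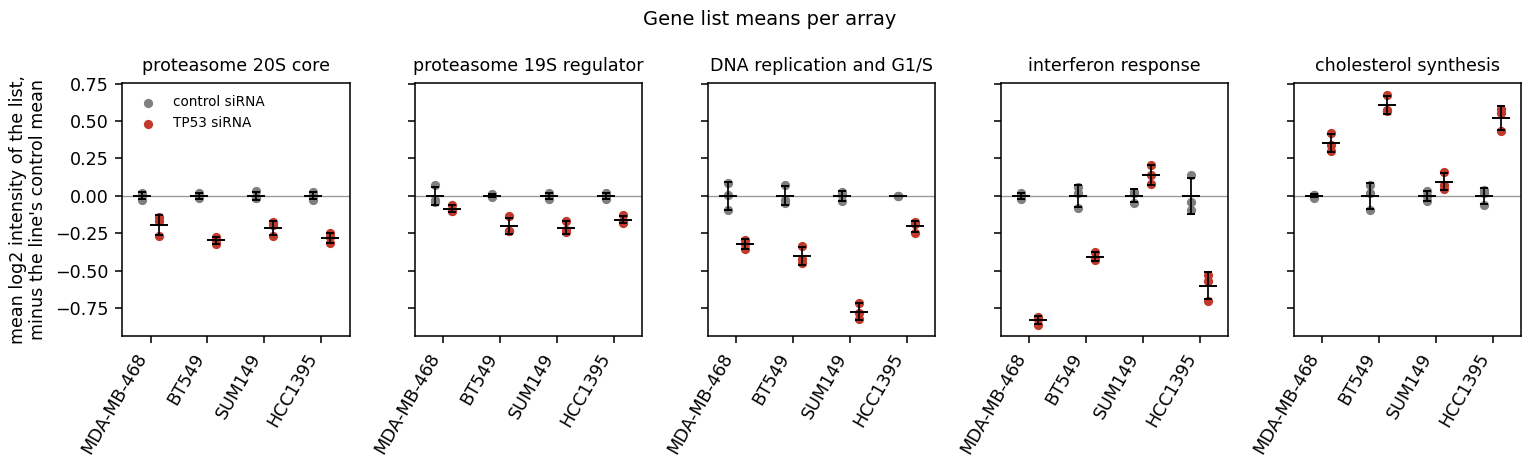
Mean log2 intensity of 5 gene lists on each array minus the mean of the control arrays of its line (vertical axis), by cell line (horizontal axis), with grey points for control siRNA and red points for TP53 siRNA. Black bars are the mean and SD of 3 arrays, and the 20S core, DNA replication and interferon lists lay lower with TP53 siRNA except for interferon in SUM149, while cholesterol synthesis lay higher.

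Among the other lists, genes of DNA replication and the G1/S transition fell most uniformly on average. Of 31 measured, 26 fell and 0 rose (28 and 0 when adjusted over the list alone), with a median of -0.42 (camera adjusted p = 2.41e-14). Examples were the replication clamp PCNA at -0.73 ± 0.06, the origin-binding ORC1 at -0.91 ± 0.08 and the ribonucleotide reductase subunit RRM1 at -0.56 ± 0.05. Of 30 genes of G2/M and mitosis, 17 fell and 3 rose (18 and 3 when adjusted over the list alone), with a median of -0.26 (adjusted p = 9.97e-07). The mitotic kinases AURKA and AURKB changed by -0.73 ± 0.03 and -0.59 ± 0.05, and the 3 that rose were MKI67, HMMR and CENPF, named after their values were seen. Of 17 genes of nucleotide synthesis 10 fell and 1 rose, also when adjusted over the list alone (median -0.15, adjusted p = 0.00504), with the thymidine kinase TK1 at -0.43 ± 0.05 and GMPS at -0.31 ± 0.04. Of 30 interferon response genes 19 fell and 0 rose, also when adjusted over the list alone (median -0.42, or -0.36 with undetected genes at their bound, adjusted p = 2.75e-09), with the membrane restriction factor IFITM1 at -0.99 ± 0.08, in arrays that included 0 untransfected samples. These calls held with an estimated correlation (adjusted p from 0.000261 to 0.0141 with an estimated correlation).

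Genes of cholesterol synthesis rose. Of 18 measured, 14 rose and 1 fell, also when adjusted over the list alone (median 0.42, camera adjusted p = 5.02e-08, and adjusted p = 0.00177 with an estimated correlation). With HMGCS1, the sterol enzymes DHCR7 at 0.63 ± 0.04 and LSS at 0.57 ± 0.04 rose, and the member that fell was INSIG1 at -0.86 ± 0.06, which retains the SREBP activation complex in the endoplasmic reticulum. Of 22 NRF2 targets, genes of the oxidative stress response, 13 rose and 3 fell (13 and 4 when adjusted over the list alone), with a median of 0.15, or 0.13 with undetected genes at their bound (adjusted p = 0.0119, and adjusted p = 0.0461 with an estimated correlation). HMOX1, heme oxygenase, rose by 0.74 ± 0.06, whereas GCLM, a subunit of the enzyme that limits glutathione synthesis, changed by -0.55 ± 0.05. Of 23 genes of the unfolded protein and integrated stress responses 11 rose and 4 fell (13 and 4 when adjusted over the list alone), with a median of 0.15 (adjusted p = 0.0119). TRIB3 rose by 0.66 ± 0.05 and SESN2 by 0.84 ± 0.10, the serine synthesis enzyme PSAT1 changed by -0.65 ± 0.04, and the average without BT549 did not pass for this list (adjusted p = 0.286).

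Of 25 p53 targets 10 rose and 3 fell, also when adjusted over the list alone, and the list did not pass. Its median was -0.02 while its mean, 0.10, and the test pointed up (adjusted p = 0.136), while fry, which makes no comparison with other genes, passed (1.34e-06). SESN2, SESN1 at 0.55 ± 0.07 and the stress gene GADD45A at 0.60 ± 0.06 rose, and so did CDKN1A, the p21 cell cycle inhibitor, at 0.34 ± 0.05, although its other probe changed by -0.14 and the mean of its probes did not pass (adjusted p = 0.121). Of 24 genes of hypoxia and glycolysis 9 fell and 3 rose, also when adjusted over the list alone, among them the mitophagy receptor BNIP3 at -0.45 ± 0.05 (median -0.09, adjusted p = 0.0466, and adjusted p = 0.288 with an estimated correlation). That call also ended when 1 of 9 arrays was left out, which were MDA-MB-468 control replicate 3, BT549 TP53 siRNA replicate 2, BT549 control replicates 1 and 2, SUM149 TP53 siRNA replicates 1 and 3, SUM149 control replicate 3, HCC1395 TP53 siRNA replicate 2 and HCC1395 control replicate 1, with an adjusted p of up to 0.0815. Of 21 heat shock chaperones 11 fell and 4 rose, also when adjusted over the list alone, with HSPA8 at -0.34 ± 0.04 and CCT5 at 0.49 ± 0.06. This list did not pass (median -0.13, adjusted p = 0.0582), although it did without background correction (0.0427), with the authors' values (0.0435), without the filter (0.0253), with array weights (0.0475) and with fry (2.13e-05). It also passed without MDA-MB-468 TP53 siRNA replicate 1 (0.0344) or BT549 control replicate 1 (0.0366).

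The remaining 7 lists did not pass on average with camera. NF-kB targets and cytokines had 6 of 23 that rose and 4 that fell (6 and 5 when adjusted over the list alone, median 0.05, adjusted p = 0.828), with the NF-kB inhibitor TNFAIP3 at -0.64 ± 0.06 and the subunit RELB at 0.38 ± 0.07. Ubiquitin and segregase genes had 5 of 14 that rose and 1 that fell (the same counts over the list alone, median 0.06, adjusted p = 0.30, with fry 0.000200), with the ligase UBE3C at 0.34 ± 0.04 and UBQLN2 at -0.32 ± 0.07. Mesenchymal markers had 5 of 21 that rose and 2 that fell (the same counts over the list alone, median 0.07, adjusted p = 0.328, with fry 0.0212), and epithelial markers 4 of 18 and 1 (the same counts over the list alone, median 0.05, adjusted p = 0.328, with fry 0.00225), with the basal keratin KRT14 at 0.85 ± 0.10. Leukocyte markers had 2 of 14 that rose and 0 that fell (the same counts over the list alone), with a median of -0.02, a mean of 0.03 and a test that pointed up (adjusted p = 0.828). Ribosomal proteins had 3 of 35 that rose and 3 that fell (3 and 2 when adjusted over the list alone), with RPL22 at 0.60 ± 0.05, a median just above 0, a mean just below 0 and a test that pointed down (adjusted p = 0.949). The p53 family and its MDM regulators had 3 of 8 that rose and 0 that fell (the same counts over the list alone), with USP7, a deubiquitinase of p53 and MDM2, at 0.33 ± 0.06, a median just below 0, a mean of 0.05 and a test that pointed up (adjusted p = 0.584, with fry 0.0184).

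**Figure D3:**
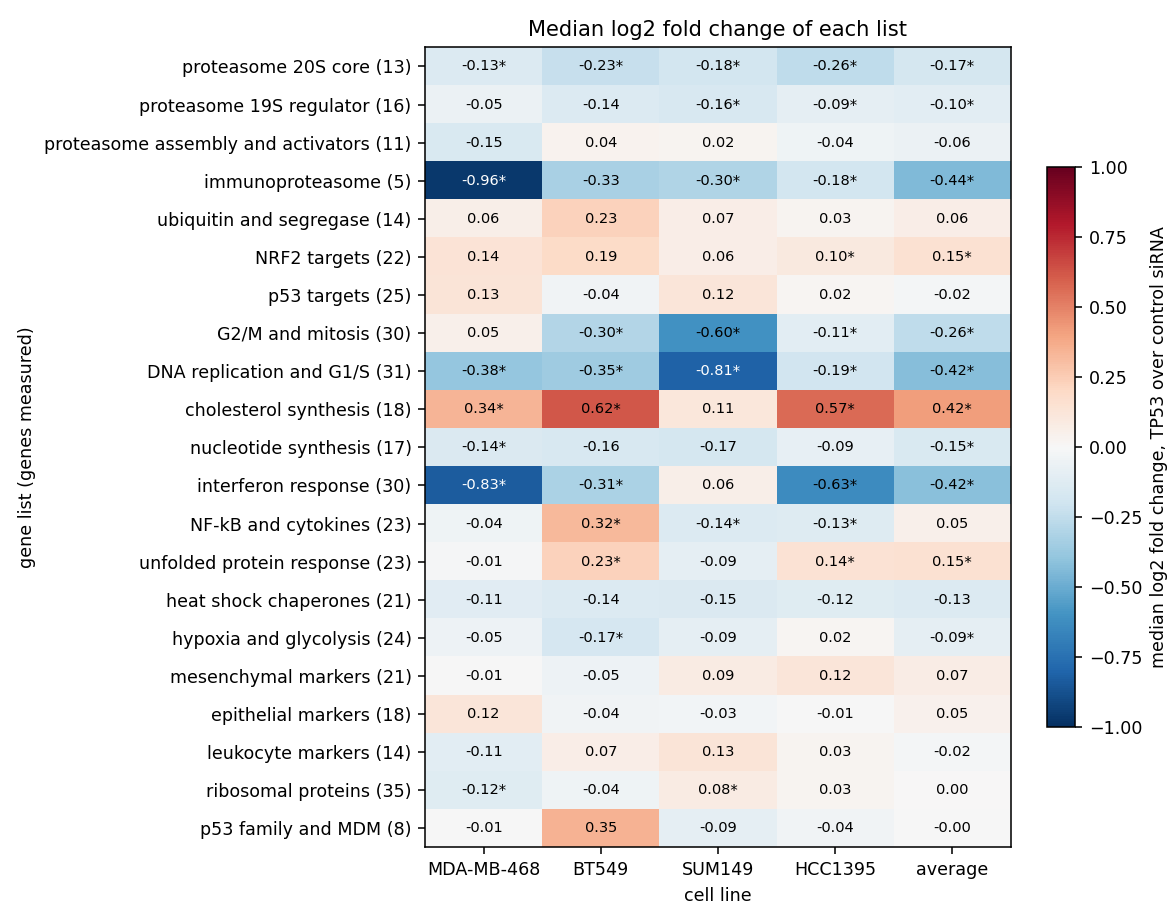
Median log2 change of each gene list (vertical axis, with the number of genes measured) in each line and on average (horizontal axis), in blue where lower and red where higher after TP53 siRNA. A star marks a camera adjusted p below 0.05, and the darkest cells are immunoproteasome in MDA-MB-468 (-0.96), interferon response in MDA-MB-468 (-0.83) and DNA replication in SUM149 (-0.81).

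In MDA-MB-468 the gene of a collagen chain rose most, and genes of the interferon response and the immunoproteasome fell. COL5A2, a chain of collagen V, rose by 3.80 ± 0.23 (adjusted p = 1.02e-09), the matrix protein THBS1 by 2.64 ± 0.15, the ectonucleotidase NT5E by 2.51 ± 0.19, the monocyte chemokine CCL2 by 2.45 ± 0.16 and SCGB2A2, mammaglobin-A, by 2.40 ± 0.17. PDLIM3 rose by 2.93 ± 0.23, and SYTL2 rose by 2.77 ± 0.21 on the probe used, with 0.11 to 0.88 on its other probes. GSTA2, a glutathione transferase with near-identical relatives, rose by 2.36 ± 0.26. Among the falls were the receptor of G-CSF, CSF3R, at -2.68 ± 0.34, CNGA2 at -2.60 ± 0.22, ICMT at -2.34 ± 0.11, the calcium-binding S100A8 at -2.27 ± 0.12, the small nucleolar RNA gene SNORA12 at -2.15 ± 0.36 and BTN3A3 at -2.14 ± 0.27. COL5A2 was detected on 2 of 3 control arrays and NT5E and GSTA2 on 1, and CNGA2 and BTN3A3 on 1 of 3 arrays after TP53 siRNA. SPRING1 was at least 3.74-fold lower and the interleukin 1 antagonist IL1RN at least 3.05-fold lower, since neither was detected after TP53 siRNA, and IL1RN did not pass without the filter on dim probes, where another of its probes was brighter (-0.26, adjusted p = 0.677).

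In this line 1103 genes rose and 1251 fell, or 16.8% of those tested. All 5 immunoproteasome genes fell (median -0.96, camera adjusted p = 1.39e-08), with PSMB9 at -1.46 ± 0.13. Of 30 interferon genes 19 fell, 23 when adjusted over the list alone, and 0 rose (median -0.83, or -0.75 with undetected genes at their bound, adjusted p = 1.48e-15), with the ISG15 ligase HERC5 at -1.62 ± 0.11 and IFITM1 at -1.68 ± 0.16. DNA replication genes fell (12 of 31, 20 when adjusted over the list alone, with 1 and 2 that rose, median -0.38, adjusted p = 4.82e-07), with the helicase subunit MCM2 at -0.70 ± 0.10. Nucleotide synthesis genes fell (6 of 17 under both adjustments, median -0.14, adjusted p = 0.00462). G2/M genes did not pass, with a median of 0.05, a mean of 0.03 and a test that pointed down (adjusted p = 0.836). Cholesterol synthesis genes rose (11 of 18, 12 when adjusted over the list alone, 1 fell, median 0.34, adjusted p = 2.55e-05). Ribosomal proteins had a median of -0.12 (3 fell and 1 rose, 2 and 1 over the list alone, adjusted p = 0.0142, and adjusted p = 0.0955 with an estimated correlation). The other calls of this paragraph held with an estimated correlation (adjusted p from 0.000469 to 0.0120 with an estimated correlation).

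In BT549 cholesterol, stress response and cytokine genes were higher and DNA replication genes lower. IL36RN, an antagonist of interleukin 36, was at least 3.91-fold higher and KMO, kynurenine monooxygenase, at least 5.30-fold higher, since neither was detected with control siRNA. SPRR2D was at least 3.28-fold higher on the probe used, with 0.49 on another, and NEDD4 rose by 2.85 ± 0.21 (0.54 on its other probe). VGLL3, a transcriptional cofactor detected on 1 of 3 control arrays, rose by 2.62 ± 0.16, the carbonic anhydrase CA4 by 2.39 ± 0.31, TAGLN by 2.35 ± 0.13 and the histone gene H4C8 by 2.30 ± 0.15. The ferritin receptor SCARA5 was at least 6.61-fold lower, SEL1L3 at least 5.47-fold, REEP2 at least 4.59-fold, the poly(A) polymerase TENT5C at least 3.73-fold and PLAAT3 at least 5.42-fold (-0.26 on its other probe). ERLIN2 changed by -3.10 ± 0.22 (-0.36 to -0.25 on its other probes), ICMT by -2.91 ± 0.11 and IGFBP4, which binds insulin-like growth factors, by -2.57 ± 0.15.

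In BT549 2010 genes rose and 2091 fell, or 29.2% of those tested. This was the most of the 4 lines in the reported fit, but the order depended on the fit. The BT549 control arrays agreed least of all groups (r of 0.980 to 0.987), with array weights of 0.28, 0.40 and 0.67. The reported fit shared 1 spread per gene over all lines, so it set no larger spread for BT549. The standard errors and p-values given for BT549 may therefore be too small. With array weights 3177 genes passed in BT549 and 4090 in MDA-MB-468, and with fits on the 6 arrays of a line 2108 in BT549 and 2239 in SUM149. Without the BT549 control replicates 1 and 2, the arrays of lowest weight, 2705 passed in BT549, 2857 in MDA-MB-468 and 3072 in SUM149. Cholesterol synthesis genes rose (12 of 18 under both adjustments, 1 fell, median 0.62, camera adjusted p = 1.59e-06), with MVD at 1.52 ± 0.15 and HMGCS1 at 1.57 ± 0.15. Unfolded protein response genes rose (10 of 23 under both adjustments, 3 fell, median 0.23, adjusted p = 0.000678), with asparagine synthetase ASNS at 1.21 ± 0.09 and the stress factor ATF3 at 1.23 ± 0.11. NF-kB targets and cytokines rose as well (10 of 23 rose and 1 fell, 12 and 2 when adjusted over the list alone, median 0.32, adjusted p = 0.00219), with LIF at 1.24 ± 0.16. DNA replication genes fell (14 of 31, 16 when adjusted over the list alone, median -0.35, adjusted p = 3.89e-05), with RRM2 at -0.95 ± 0.12. These 4 lists held with an estimated correlation (adjusted p from 0.00570 to 0.0300 with an estimated correlation). The following calls did not hold in that test. G2/M genes fell (14 of 30 with 3 that rose under both adjustments, median -0.30, adjusted p = 0.00315, 0.0715 without control replicate 3, and adjusted p = 0.113 with an estimated correlation). Interferon genes fell (9 of 30 under both adjustments, median -0.31, or -0.08 with undetected genes at their bound, adjusted p = 0.00161, and adjusted p = 0.0749 with an estimated correlation), with IFIT1 at least 2.46-fold lower. Hypoxia genes fell (9 of 24 with 1 that rose under both adjustments, median -0.17, or -0.13 with undetected genes at their bound, adjusted p = 0.0115, 0.0583 without TP53 siRNA replicate 2, and adjusted p = 0.156 with an estimated correlation), with the glucose transporter SLC2A1 at -1.14 ± 0.09.

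SUM149 had the lowest list medians for cell cycle genes of the 4 lines. DNA replication genes fell in 23 of 31 cases (25 when adjusted over the list alone, with 0 and 1 that rose), with a median of -0.81 (camera adjusted p = 2.76e-21). Examples were MCM6 at -1.02 ± 0.09 and the phosphatase CDC25A at -1.44 ± 0.14. G2/M genes fell in 21 of 30 cases (25 when adjusted over the list alone), and 0 rose, with a median of -0.60 (adjusted p = 1.15e-17). Examples were AURKA at -0.99 ± 0.07 and cyclin A2, CCNA2, at -0.96 ± 0.10. Among the genes that rose most were the microRNA gene MIR205 at 2.47 ± 0.23 on its listed probe, SHISA2 at 2.38 ± 0.14 (adjusted p = 2.84e-09), CLCA2 at 2.35 ± 0.24, the basal keratin KRT14 at 2.32 ± 0.19, CBLN2 at 2.22 ± 0.31 and the lipid carrier APOE at 2.21 ± 0.15. MIR205 was detected on 2 of 3 control arrays and CBLN2 on 1. H4C8 was at least 3.06-fold higher and SERPINA6, the corticosteroid-binding globulin, at least 3.41-fold higher. The poly(A) polymerase TENT5B changed by -2.78 ± 0.17, the clock gene PER1 by -2.26 ± 0.23, IPO5 by -2.21 ± 0.22, the acute phase gene SAA2 by -2.05 ± 0.14 and TMPRSS3 by -2.04 ± 0.17, with -1.50 to 0.45 on its other probes. TENT5B and IPO5 were detected on 2 of 3 arrays after TP53 siRNA and PER1 on 1. TMEM87B was at least 3.99-fold lower and the homeobox gene MEOX1 at least 3.44-fold lower, and CCL3L3, a chemokine with near-identical copies, changed by -2.02 ± 0.18.

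In this line 1117 genes rose and 1413 fell, or 18.0% of those tested. The calls of DNA replication and G2/M held with an estimated correlation (adjusted p = 2.28e-05 and 0.000351 with an estimated correlation). NF-kB targets and cytokines fell (6 of 23 with 1 that rose under both adjustments, median -0.14, or -0.07 with undetected genes at their bound, adjusted p = 0.0201, and adjusted p = 0.101 with an estimated correlation), with TNFAIP3 at -1.47 ± 0.12 and the chemokine CCL20 at -1.41 ± 0.16, and the list did not pass without control replicate 2 (0.0802) or 3 (0.0863). Immunoproteasome genes had a median of -0.30 (3 of 5 fell under both adjustments, adjusted p = 0.0201, and adjusted p = 0.170 with an estimated correlation), which ended without control replicate 3 (0.0535) or TP53 siRNA replicate 2 (0.0523). Ribosomal proteins had a median of 0.08 (2 of 35 rose, 1 over the list alone, adjusted p = 0.0201, and adjusted p = 0.146 with an estimated correlation), with RPL22 at 0.64 ± 0.09. Interferon genes did not pass (6 of 30 rose and 1 fell, 8 and 3 when adjusted over the list alone, median 0.06, adjusted p = 0.126, with fry 0.0161). The members that rose included IFIT2 at 1.42, IFIT1 at 1.08 and IFIT3 at 0.84, named after their values were seen. Cholesterol synthesis genes did not pass (3 of 18 rose and 2 fell, 4 and 2 when adjusted over the list alone, median 0.11, adjusted p = 0.315).

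HCC1395 had the smallest number of changed genes, and the largest falls included several shared with the other lines. SPRING1, detected on 2 of 3 arrays after TP53 siRNA, changed by -3.07 ± 0.20 (adjusted p = 9.1e-09), ICMT by -2.11 ± 0.11, and ERLIN2 by -2.08 ± 0.22 (-0.37 to -0.26 on its other probes). TMEM30A changed by -2.07 ± 0.24, IPO5 by -1.88 ± 0.22 and POLR1H by -1.69 ± 0.11. SLC35G1 changed by -1.67 ± 0.19 and the membrane protein EMP1 by -1.65 ± 0.09. NEDD4 rose by 2.07 ± 0.21 (0.02 on its other probe), the actin regulator WASF3 by 1.59 ± 0.21, FGFBP1, a carrier of fibroblast growth factors, by 1.48 ± 0.20, and HMGCS1 by 1.42 ± 0.15. VPS4B rose by 1.29 ± 0.11, the sterol desaturase SC5D by 1.22 ± 0.18 and the receptor ROR1 by 1.20 ± 0.16. TMEM30A and SLC35G1 were detected on 2 and 1 of 3 arrays after TP53 siRNA, and WASF3 on 1 of 3 control arrays. ALG10B, a glucosyltransferase, rose by 1.42 ± 0.31 on the probe used, with -0.17 to 0.29 on the others.

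In this line 492 genes rose and 532 fell, or 7.30% of those tested, and the total fell to 644 without TP53 siRNA replicate 1, 670 without TP53 siRNA replicate 3, 663 without control replicate 2 and 639 without control replicate 3. Cholesterol synthesis genes rose (11 of 18, 14 when adjusted over the list alone, 1 fell, median 0.57, camera adjusted p = 1.60e-12), with LSS at 0.81 ± 0.08. Unfolded protein response genes rose (9 of 23, 11 when adjusted over the list alone, 1 fell, median 0.14, adjusted p = 6.90e-05), with TRIB3 at 0.85 ± 0.11. Interferon genes fell (16 of 30, 17 when adjusted over the list alone with 1 that rose, median -0.63, adjusted p = 1.35e-15), with the antiviral GTPase MX1 at -0.83 ± 0.11 and IFIT1 at -1.43 ± 0.21. NF-kB targets and cytokines fell (8 of 23 under both adjustments, median -0.13, adjusted p = 0.00102), with CXCL8 at -0.82 ± 0.12 and IL6 at -1.02 ± 0.15. DNA replication genes fell as well (3 of 31, 4 when adjusted over the list alone, median -0.19, adjusted p = 5.46e-05), with PCNA at -0.57 ± 0.11. These 5 lists held with an estimated correlation (adjusted p from 0.000231 to 0.0148 with an estimated correlation).

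The following calls in HCC1395 did not hold with an estimated correlation. G2/M genes had a median of -0.11 (2 of 30 fell under both adjustments, adjusted p = 0.0218, 0.0575 without TP53 siRNA replicate 3, and adjusted p = 0.190 with an estimated correlation), with AURKA at -0.58 ± 0.07. NRF2 targets had a median of 0.10 (5 of 22 rose and 1 fell, 6 and 1 when adjusted over the list alone, adjusted p = 0.0376, and adjusted p = 0.119 with an estimated correlation), with HMOX1 at 0.67 ± 0.11 and GCLM at -0.85 ± 0.10. This call ended without control replicate 1 (0.0644) or 2 (0.0706) or TP53 siRNA replicate 2 (0.0579) or 3 (0.0845). Immunoproteasome genes had a median of -0.18 with 0 of 5 past the test under both adjustments (adjusted p = 0.0283, and adjusted p = 0.190 with an estimated correlation). That call ended without control replicate 2 (0.0858) or TP53 siRNA replicate 2 (0.0785) or 3 (0.0571).

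**Figure D4:**
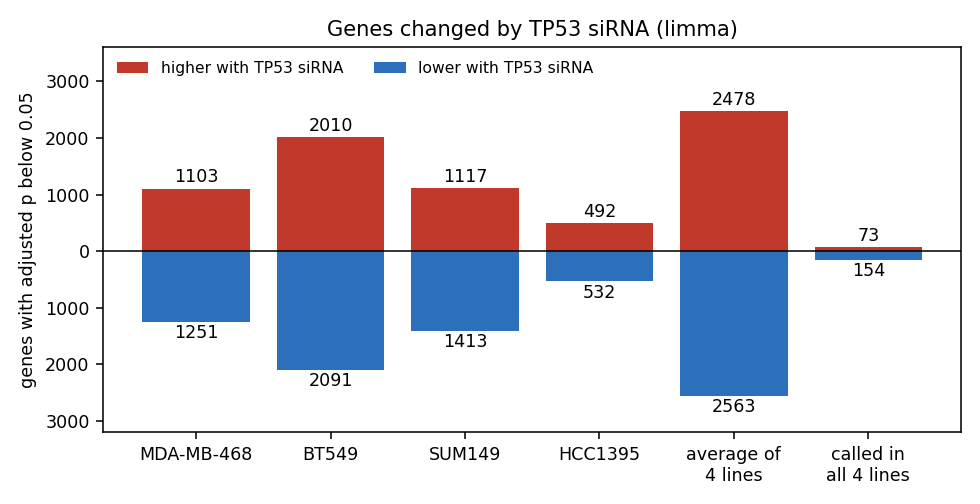
Number of genes with an adjusted p below 0.05 (vertical axis) that were higher (red, upward) or lower (blue, downward) after TP53 siRNA in each line, on average and in all 4 lines (horizontal axis), from 3 arrays per group. Counts ran from 492 higher and 532 lower in HCC1395 to 2010 and 2091 in BT549 in the reported fit, and the order of the other lines and BT549 depended on the fit.

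The pairs of lines shared more calls of one direction than independence gives. MDA-MB-468 and HCC1395 shared 189 genes that rose and 264 that fell, 4.89 and 5.57 times the expected numbers. BT549 and SUM149 shared 428 and 633, at 2.67 and 3.01 times. The other pairs had ratios from 2.68 to 4.70, and the adjusted p of Fisher's exact test ranged from 3.02e-196 to 5.31e-60 over 12 tests. Genes are not independent replicates, so these p-values describe the overlap across genes only. The lines had separate control arrays but shared 1 estimate of the spread per gene. Across genes the changes of 2 lines correlated with Pearson's r of 0.217 to 0.392 and Spearman's rho of 0.211 to 0.351. Without 1 array the shared calls of BT549 and HCC1395, 648 in all, fell to 430 (HCC1395 TP53 siRNA replicate 1) or 425 (HCC1395 control replicate 3). Genes called in opposite directions numbered 34 for MDA-MB-468 and HCC1395 and 161 for BT549 and SUM149.

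The response also differed between lines, for interferon, cell cycle, cholesterol, cytokine and unfolded protein response genes among others. The F test of the interaction passed for 3346 genes, 23.8% of those tested, and 404 genes were called in opposite directions in at least 1 pair of lines. Of the genes called on average, 2952 did not pass the interaction test and 2089 did. SEL1L3 was at least 5.47-fold lower in BT549 and changed by 0.39, 0.14 and 0.43 in MDA-MB-468, SUM149 and HCC1395 (interaction adjusted p = 4.15e-13). IL36RN was detected after TP53 siRNA in BT549 and under neither siRNA in the other lines (2.97e-12). DKK1, an inhibitor of Wnt signalling, changed by 2.28 in MDA-MB-468 and -0.84 in HCC1395 (5.43e-11), RAB11FIP1, an endosomal recycling protein, by 0.90 in MDA-MB-468 and -1.08 in BT549 (2.68e-09), and THBS1 by 2.64 in MDA-MB-468 and -1.28 in SUM149 (2.82e-09). The transcription factor FOXQ1 changed by -1.98 in MDA-MB-468 and 1.15 in SUM149 (6.69e-09), the vasodilator ADM by 1.47 and -0.61 (6.86e-09) and S100A8 by -2.27 and 0.08 (1.27e-08) in these lines.

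Of 126 tests of lists between pairs of lines 30 passed. With an estimated correlation 21 of them held. The NF-kB and unfolded protein response lists differed in 4 pairs each and DNA replication in 3, and all of these held. Interferon differed in 5 pairs, of which 3 held, G2/M in 4, of which 3 held, and cholesterol in 4, of which 2 held. Immunoproteasome differed in 3 and ribosomal proteins in 2, of which 1 each held, and hypoxia in 1, which did not hold. MDA-MB-468 and SUM149 differed most for interferon genes (median difference of log2 changes -0.93, adjusted p = 1.07e-13) and for G2/M genes (0.74, 1.07e-13), while DNA replication genes differed most between SUM149 and HCC1395 (-0.61, 1.07e-13). Cholesterol genes differed between BT549 and SUM149 (0.56, 6.54e-06), as did unfolded protein response genes (0.38, 6.54e-06) and NF-kB targets (0.64, 1.02e-06). The 9 that did not hold included immunoproteasome genes between MDA-MB-468 and SUM149 (-0.73, adjusted p = 0.000265, and adjusted p = 0.0557 with an estimated correlation) and hypoxia genes between BT549 and HCC1395 (-0.15, adjusted p = 0.0117, and adjusted p = 0.271 with an estimated correlation). For MDA-MB-468 against BT549 the adjusted p-values with an estimated correlation were 0.0557 for immunoproteasome, 0.189 for G2/M, 0.134 for cholesterol and 0.0632 for interferon. Cholesterol between MDA-MB-468 and SUM149 had 0.118, and between MDA-MB-468 and HCC1395 interferon had 0.288 and ribosomal proteins 0.0774. Line, p53 substitution and, for some lines, medium varied together, so a difference between lines could not be assigned to any 1 of them.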

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

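The tests of off-target silencing, of other probes, of dividing cells and of the control siRNA were chosen only after the result was seen.

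In the response shared by the 4 lines, 154 genes fell in every line, among them ICMT (-2.33) and ERLIN2 (-2.25), and SPRING1, not detected after TP53 siRNA in 3 lines, at least 3.10-fold on average. Hybridization peculiar to single probes was argued against as the whole cause for the 58 of these genes that had other kept probes. Of these 76 other probes 96.1% also changed downward (median -0.53 against -0.80 for the probes used, with 52.1% downward among the other probes of all genes). The remaining genes, ICMT and SPRING1 among them, had no other kept probe and were not covered, and the other probes of ERLIN2 and SEMA4F changed little or upward. Off-target silencing, in which an siRNA acts on transcripts other than its target in every cell type, may account for part of the pattern and stays open. It predicts that large changes alike in all lines are mostly falls, and 76.9% of the 26 such genes fell, but 17 of these 20 falls were among the 154 genes that prompted the test, so the share decides nothing. A response to the loss of p53 itself also stays open, since 1 TP53 siRNA treatment was compared with 1 control treatment and siRNA sequences were not used here.

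The 20S core list fell on average, with a mean of -0.25. A trend of the change with signal intensity was argued against, because 0% of 10000 random lists matched for signal had a mean as low, and the lowest was at -0.23. A smaller share of dividing cells may account for the fall and stays open. Scaled by the fall of DNA replication genes, the SUM149 change would give -0.06 in HCC1395, where the mean was -0.28, a difference of -0.22 ± 0.03 (SE), but this assumes a fixed proportion between the 2 lists in both lines, which was not measured. Of 100 regroupings of the arrays within lines, only the real one gave so small a camera p for this list, by a narrow margin (-log10 p of 4.89 against 4.88 for the next). With so close a second value, the regroupings did not exclude chance for this list. For the 19S list 6 of the 100 regroupings, the real one included, gave a p as small (2.32 against a highest of 3.32), so that chance was not excluded, and off-target silencing of single subunits such as PSMA2 or PSMC1 was not tested.

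The interferon response list fell in MDA-MB-468, BT549 and HCC1395 and not in SUM149, with the largest difference between MDA-MB-468 and SUM149 at -0.93, and the call in BT549 did not hold with an estimated correlation (adjusted p = 0.0749). Absence of interferon transcripts from SUM149 was argued against, since 96.7% of the list, 29 of 30 genes, were detected in its control arrays, compared with 27, 22 and 28 in MDA-MB-468, BT549 and HCC1395. An interferon response set off by the control siRNA, which would make TP53 siRNA arrays appear low in lines that sense it, cannot be told apart from a fall caused by TP53 siRNA, because the series as used here had 0 untransfected arrays. Differences between the lines in p53 substitution, medium or other background also stay open and were not tested.

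Other lists also differed between lines by the test of the difference. The immunoproteasome list differed by -0.73 between MDA-MB-468 and SUM149, a call that did not hold (adjusted p = 0.0557 with an estimated correlation). Its difference of -0.68 between MDA-MB-468 and HCC1395 did hold (camera adjusted p = 7.76e-07, and adjusted p = 0.0112 with an estimated correlation). G2/M and mitosis differed by 0.74 between MDA-MB-468 and SUM149, and ribosomal proteins by -0.27 (adjusted p = 6.79e-05). Cholesterol synthesis differed by 0.56 between BT549 and SUM149, the unfolded protein response by 0.38 and NF-kB and cytokines by 0.64. DNA replication and G1/S differed by -0.61 between SUM149 and HCC1395. Hypoxia and glycolysis differed by -0.15 between BT549 and HCC1395, a call that did not hold either (adjusted p = 0.271 with an estimated correlation).

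By the interaction test 3346 genes differed between lines. The smallest adjusted p-values were those of SEL1L3 (4.15e-13), IL36RN (2.97e-12), DKK1 (5.43e-11), RAB11FIP1 (2.68e-09), THBS1 (2.82e-09), FOXQ1 (6.69e-09), ADM (6.86e-09) and S100A8 (1.27e-08). Outside the genes compared, 826 of the 7177 kept probes without a listed gene, or 11.5%, passed for the average over lines.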

How the results depend on the processing

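The comparisons without 2 BT549 control arrays and without the BT549 line were chosen only after the result was seen. Under the alternatives fixed beforehand, excluding single left-out arrays, 130 counts of genes stayed within 1.5 times the reported count and 30 moved further. For lists, 708 values kept direction and side of the threshold, 18 passed newly, 24 no longer passed and 9 changed direction. For named genes the numbers were 3724, 71, 49 and 0. The lists and genes that changed direction had not passed in the reported fit, except SLC2A1 and ELF3 in the average without BT549. Signal over background limits dim genes: 14031 genes were tested, 20043 without the filter and 11797 with the stricter one.

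With an adjusted p below 0.01, a stricter threshold, 1339, 2707, 1475 and 470 genes passed in MDA-MB-468, BT549, SUM149 and HCC1395, 117 in all 4 lines and 1840 in the interaction test. The shared calls were then 570 for MDA-MB-468 and BT549, 326 for MDA-MB-468 and SUM149, 227 for MDA-MB-468 and HCC1395, 583 for BT549 and SUM149, 311 for BT549 and HCC1395 and 196 for SUM149 and HCC1395. With a change of at least 1.5-fold, also stricter, the counts were 1167, 2383, 1372 and 512 in the lines, 601 on average and 71 in all 4, and the shared calls in the same order 389, 218, 160, 423, 270 and 154. In all 4 lines 14 then rose and 57 fell. With array weights 4090, 3177, 3101 and 1752 genes passed in MDA-MB-468, BT549, SUM149 and HCC1395, so that BT549 no longer had the most, and the shared calls were 1032 for MDA-MB-468 and SUM149, 800 for MDA-MB-468 and HCC1395 and 675 for SUM149 and HCC1395. The cause was not tested. A fit on the 6 arrays of a line, with fewer samples for the spread, gave 2108 genes in BT549, fewer than the 2239 in SUM149, and an adjusted p of 0.0595 for the 20S list in MDA-MB-468. Without the 2 BT549 controls of lowest weight, with fewer samples, 2705 genes passed in BT549, 2857 in MDA-MB-468 and 3072 in SUM149. In the other settings BT549 had the most genes, and in all settings HCC1395 had the fewest.

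With an estimated correlation the 20S list had an adjusted p of 0.0955 in MDA-MB-468, 0.0506 in BT549 and 0.0972 in SUM149, and the 19S list 0.0588 in SUM149. With fry, which makes no comparison with other genes, the 19S list passed in MDA-MB-468 (0.00184) and BT549 (9.84e-07). The list of assembly factors in SUM149 changed direction without background correction (adjusted p = 0.979), without the filter (0.965), in the fit on one line (0.919) and with fry (0.986). Ribosomal proteins on average changed direction without background correction (0.998), with neqc within lines (0.984), with fry (0.746) and without BT549 (0.897). NF-kB and cytokines on average did so with fry (0.865) and without BT549 (0.131), and the p53 family without BT549 (0.781). Without BT549 the average changes of SLC2A1 (0.068), ELF3 (-0.14) and CD74 (0.44) also took the other sign. The cause was not tested.

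Leaving out 1 array at a time gave between 639 and 1210 genes in HCC1395, between 425 and 757 shared calls of BT549 and HCC1395, and adjusted p-values of 0.00899 to 0.0607 for the 20S list in MDA-MB-468. The list of assembly factors in SUM149 (0.633 to 0.998) and ribosomal proteins on average (0.776 to 0.997) changed direction and did not pass. IL36RN ranged from -0.0079 to 0.052 in SUM149 and from -0.047 to 0.064 in HCC1395, where it was not detected, and RAB11FIP1 from -0.012 to 0.11 in SUM149.

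With the replicate number as a replicate block, 2233, 4164, 2472 and 947 genes passed in MDA-MB-468, BT549, SUM149 and HCC1395, 5093 on average and 214 in all 4 lines. The list of assembly factors in SUM149 changed direction (0.922), and NRF2 targets in HCC1395 (0.0918) and hypoxia on average (0.0566) no longer passed. By correlation with the control arrays, 5 of 12 TP53 siRNA arrays went best with their own number: all 3 in MDA-MB-468 (r of 0.417, 0.234 and 0.0964), 1 in BT549, 1 in SUM149 and 0 in HCC1395. This is a hint of pairing in MDA-MB-468 from the data, not the design, and not every r there was over 0.1. A fit with the slide as block was not run.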

Other observations

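The test of histone genes against DNA replication genes was chosen only after the result was seen, while the regroupings were fixed beforehand.

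Of the histone genes tested more rose than fell, while DNA replication genes fell. The family tested held H1-1, H1-2, H1-3 and the genes whose symbols start with H2AC, H2BC, H3C or H4C. Other histone genes were left out, among them H2AZ1, which fell in all 4 lines (-0.37 on average). Of the 47 measured genes of the family 22 rose and 4 fell on average, with a median of 0.24. The line medians were 0.20 in MDA-MB-468, 0.55 in BT549, 0.37 in SUM149 and 0.20 in HCC1395. The median stayed positive without background correction (0.10), with the authors' values (0.11) and with neqc within lines (0.24). Fewer cells in S phase would lower both groups if the probes read the replication-dependent histone transcripts, which are made in S phase. The histone family instead had a camera p of 7.01e-08 in the upward direction (0.0158 with an estimated correlation). Without the 3 histone genes named for their large rises, the other 44 still had a median of 0.23 and rose (camera p of 1.03e-05, and 0.0343 with an estimated correlation). Which histone transcripts the probes read was not tested, so the rise does not decide whether fewer S-phase cells were the whole cause of both changes. More polyadenylated histone transcripts may be a candidate explanation for the rise and was not tested, and near-identical copies may share probes.

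Some list members moved in opposite directions between lines or against most of their list. CD74, the invariant chain of antigen presentation, was at least 3.08-fold lower in BT549, where it was not detected after TP53 siRNA, and changed by 1.37 in SUM149. CENPF, a kinetochore protein, rose by 1.76 in BT549, where most G2/M genes that passed fell.

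Arrays were regrouped within lines to set the real grouping against others. Each line allowed 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 2354 genes in MDA-MB-468, 4101 in BT549, 2530 in SUM149 and 1024 in HCC1395, and the highest of the others gave 3, 3, 4 and 3. Over several lines 100 regroupings were drawn, and for each of the following counts only the real one reached its value. This sets the real grouping apart from the others. Groups that mix the siRNAs hold any siRNA effect in their spread, which lowers their counts. The counts of the other groupings therefore do not show how many genes chance gives. On average over lines 5041 genes passed against a highest of 1391 in the others, in all 4 lines 227 against 0, and in the interaction test 3346 against 643. Shared calls numbered 1029 for MDA-MB-468 and BT549 against a highest of 459, 643 for MDA-MB-468 and SUM149 against 1, and 453 for MDA-MB-468 and HCC1395 against 17. They numbered 1061 for BT549 and SUM149 against 1, 648 for BT549 and HCC1395 against 114, and 413 for SUM149 and HCC1395 against 16.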
